A study of Rattus norvegicus with 10 samples.

How the data were processed

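Hippocampal RNA of 10 rat libraries, 5 sham and 5 TBI, was sequenced after poly-A selection on an Illumina HiSeq, per the labels' protocols. The authors deposited FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of the library), with a status word beside each value. Per the submitters' processing notes, TopHat, TopHat2, Bowtie, Bowtie2, Cufflinks and Cuffdiff and the rn5 build of the rat genome were used, with neither roles nor versions given. Annotation and filters are not given in the sources used here. The deposited columns had 75th percentiles of 13.1 to 13.5 FPKM while their sums differed, so the values had been scaled between libraries. FPKM divides by an estimated locus length and by a library total, so a very abundant transcript such as Ttr in some libraries can lower the others unless scaling corrects it. Values were continuous and whole reads could not be recovered, so no count test was run and the depth is unknown. The values carry no strand information, so overlapping and antisense genes cannot be told apart. A status other than OK (FAIL or HIDATA) stood at 81 of the 25269 loci in at least 1 library, 68 of them tested, and these values were used as deposited.

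Groups were taken from the treatment in the labels, and libraries carry the numbers 1 to 5 of their titles. No 2 columns held identical values, and Spearman correlations across loci between libraries ran from 0.900 to 0.984. Of the loci, 7177 name no gene and 406 name several, and 1352 gene names stand on more than 1 locus. Loci without a name were tested too, 4705 of the 16889, since they carry measurements and no library total was computed here. Coordinates are not printed, since the values come without them.

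The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean trend, two-sided) on log2(FPKM + 0.5), with loci of mean FPKM of at least 0.5 and a Benjamini-Hochberg adjusted p under 0.05. A log2 difference on this scale understates the change of low genes. Gene lists were tested with camera, with a preset correlation of 0.01 and with an estimated one, and with fry. List scores, the mean of the centred log2 values of the members, were compared by an exact two-sided permutation test over all 252 assignments, whose smallest possible p is 0.00794. Of 29 lists with 856 members, 783 members matched a locus and 713 were tested. The list of mitochondrially encoded genes had fewer than 5 tested members and gave no test. Symbols were matched without regard to case, and a locus naming several genes was used for 17 members where the genes were of one family. Of the list symbols, 5 were replaced by synonyms, all 5 checked in a gene table of another rat assembly, GRCr8, used only for names. The rule for shared loci and the synonyms were set after the symbols of the table had been seen.

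The comparison, lists, naming rule and most alternatives were fixed before the data were examined. The rule names, in each direction, up to 12 genes past adjustment with a mean of at least 1 FPKM, and where fewer pass, the genes with the smallest p up to 5 in all. It adds 2 to 4 members with the smallest p of each list described, and the markers Gfap, Aif1, Cd68, Vim, Bdnf, Slc17a7, Gad1, Mbp and Ttr. After a first look at the values, this was read as loci that name a gene and have a mean of at least 1 FPKM, with 3 members for lists past camera's test and 2 for other lists. Some of the genes so chosen are not used here.

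The procedure was tested on simulated data drawn from the observed means and residual spreads of the 16889 loci, with independent loci and 200 changed in each of 5 draws. It recovered 72.0% of the 2-fold changes and 92.4% of the 4-fold changes, and 4.97% of its calls were false. In the real libraries loci vary together and the number of changed loci is unknown. These rates therefore cannot be carried over to the real comparison. Alternatives covered the pseudocount, the filter, scaling, the variance model, array weights, a replicate block, a hidden component as covariate, each library left out, and other tests. A count test, edgeR, was planned only for recoverable reads and was not run. Chosen after seeing the data were a term for the libraries numbered 1, libraries 2 to 5 alone (also without sham 4, and also on named loci only), choroid plexus and matrix scores as covariates (together and each alone), and sums over loci of the same gene. A term for each of the 25 pairs of a sham and a TBI library, and a scan of all 45 pairs of libraries, followed the observation that Scd differed in sham 1 and TBI 1.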

Results

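Messenger RNA of the rat hippocampus was measured by poly-A RNA sequencing 1 week after surgery. The animals were male Sprague-Dawley rats that received either a traumatic brain injury (TBI) or sham surgery. The injury was made by fluid percussion, in which a pressure pulse of fluid strikes the exposed dura. A learning test preceded tissue collection. There were 10 libraries, 5 from sham rats and 5 from injured rats. Nothing in the labels says outright that each library came from a separate animal, so p-values measure the spread between these libraries. The values were FPKM for 25269 loci, of which 16889 had a mean of at least 0.5 and were tested. The sum of FPKM per library lay between 523239 and 629660. The read depth behind the values is unknown, so no counting interval is given, and precision was taken from the spread between libraries.

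The comparison of injured with sham hippocampus asks which genes differ 1 week after the injury. Complement C3, the central protein of the complement cascade, was measured at 2.26 ± 0.612 FPKM in sham and 7.39 ± 4.39 after TBI (SD, n = 5 each). Claudin-5 (Cldn5), a tight junction protein of brain endothelium, was at 68.3 ± 8.49 FPKM in sham and 49.2 ± 3.76 after TBI, with all 5 injured libraries below all 5 sham libraries. Plac9 was at 28.2 ± 15.0 FPKM in sham and 2.07 ± 1.11 after TBI, again without overlap. None of these differences passed limma's test after Benjamini-Hochberg adjustment over the 16889 loci, where 0 loci passed and the smallest adjusted p was 0.781. At an unadjusted p under 0.05 there were 477 loci, 227 higher and 250 lower after TBI, against 844 expected by chance. Groups did not overlap at 38 loci that were higher and 40 that were lower, 0.462% of those tested against 0.794% by chance. An exact permutation test of each locus called 0 after adjustment, but it could hardly have called any. Its smallest possible p was 0.00794, which passes adjustment over 16889 loci only if far more than the 78 observed loci reach it. This 0 therefore adds no evidence for an absence of change. The median half-width of the 95% interval was 0.33 on the log2 scale, and for 89.3% of loci the whole interval lay within 1 unit either way. Because 0.5 was added to each value, 1 unit is more than 2-fold in FPKM at low loci.

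The locus with the smallest p, XLOC_007422, carries no gene name. It was at 26.3 ± 3.18 FPKM in sham and 14.8 ± 2.35 after TBI, a log2 difference of -0.82 (SE 0.12) with limma's adjusted p = 0.781, and was lower in 5 of 5 injured libraries. Limma's adjusted p was 0.0547 with the term for the libraries numbered 1, 0.102 with array weights and 0.233 with libraries 2 to 5. Without the mean trend it was 0.990. None of these passed.

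Of the named genes with the smallest p, 5 were higher after TBI. C3 (XLOC_023430) had a log2 difference of 1.35 (SE 0.36, 95% interval 0.55 to 2.15) and Mreg, which encodes melanoregulin, of 0.74 (SE 0.21). Odf3b differed by 0.54, Kcnk13, a potassium channel, by 0.53, and RGD1563216 by 0.52. In each of these 5 genes all 5 injured libraries lay above the sham mean on the log2 scale, and in Odf3b and Kcnk13 the groups did not overlap. The 5 genes with the smallest p among those lower after TBI were Plac9 (XLOC_009157, log2 difference -3.29, SE 0.58), Grm2, a metabotropic glutamate receptor (-0.79), Arid5a, which stabilizes inflammatory messenger RNAs (-0.49), Cldn5 (XLOC_005868, -0.46) and Tm2d3 (-0.31). All 5 injured libraries lay below the sham mean in each of them. The adjusted p of all 10 genes was 0.988 in limma's test. Plac9 depended on a single sham library: sham 4 was at 4.22 FPKM where the others were at 25.3 to 43.2, and without it Plac9 passed with an adjusted p of 0.00895 and a log2 difference of -3.86. With libraries 2 to 5 but not sham 4 its adjusted p was 0.0552, and over the other alternatives it reached up to 1.00.

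**Figure D1:**
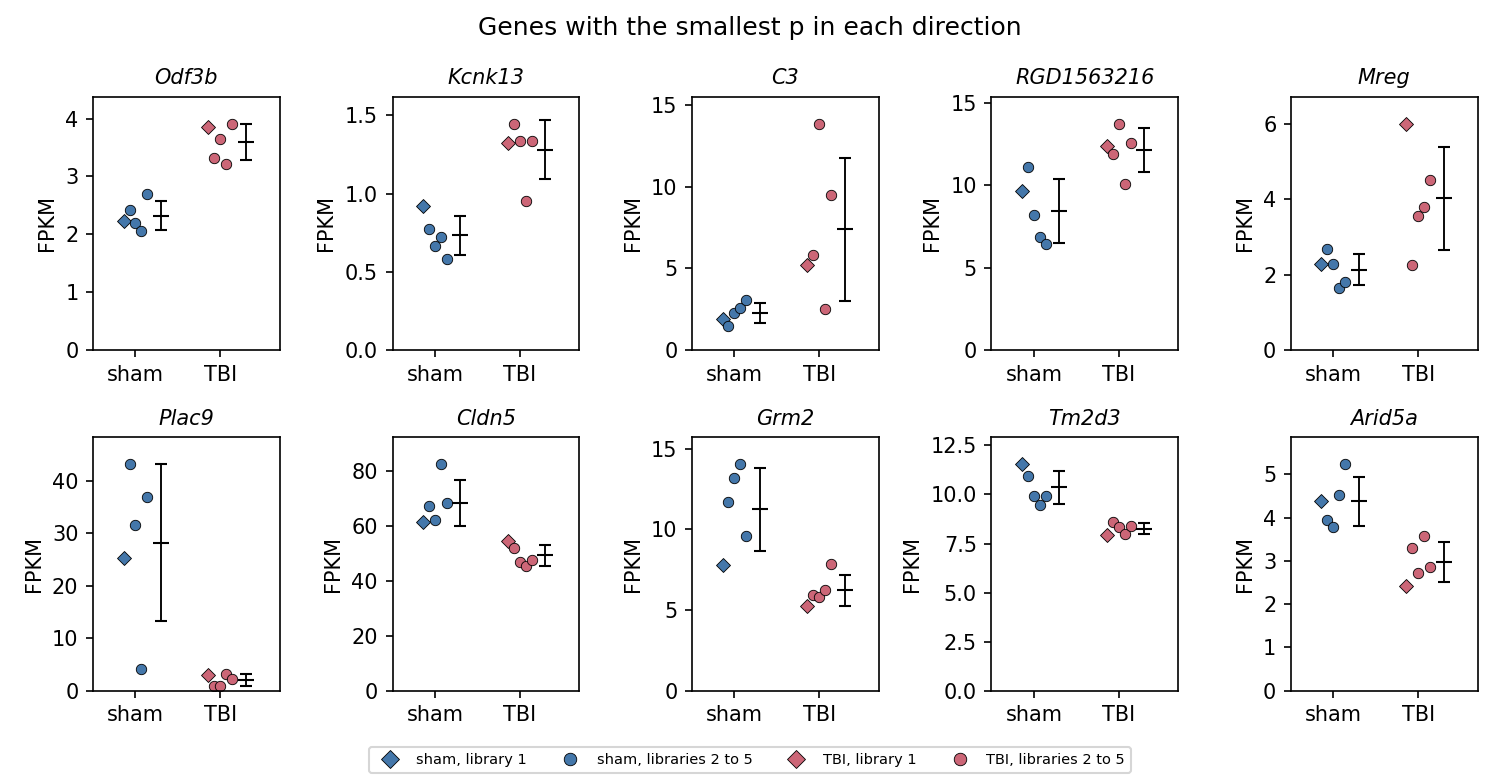
FPKM of the 10 named genes with the smallest p, 5 higher (upper panels) and 5 lower (lower panels) after TBI, with each point 1 library on a linear axis from 0 and bars giving mean ± SD of 5 libraries. Cldn5 lies between 45.3 and 54.3 FPKM in the injured libraries and between 61.3 and 82.4 in sham, and C3 reaches 13.9 in 1 injured library; none of the 10 passed adjustment.

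The markers chosen before the data were examined differed by less than the spread between libraries. Gfap, the intermediate filament of astrocytes, was at 341 ± 104 FPKM in sham and 335 ± 130 after TBI (log2 difference -0.06, 95% interval -0.66 to 0.54). Aif1, the microglial protein Iba1, was at 24.7 ± 4.23 and 27.2 ± 5.70. Cd68, a lysosomal protein of phagocytes, was at 1.82 ± 1.28 and 3.60 ± 3.57, and Vim at 76.1 ± 61.0 and 69.7 ± 44.6. For neurons, the growth factor Bdnf was at 12.3 ± 1.73 and 11.5 ± 2.47, the glutamate transporter Slc17a7 at 858 ± 105 and 837 ± 193, and the GABA-synthesizing enzyme Gad1 at 65.1 ± 15.3 and 69.9 ± 11.5. The myelin protein Mbp was at 2704 ± 628 and 2556 ± 666. Adjusted p in limma's test was 0.988 or above for each. The small differences of Gfap, Vim, Slc17a7 and Mbp changed sign when a single library was left out, and those of Gfap and Slc17a7 also under quantile normalization.

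Gene lists fixed before the data were examined showed group-wide shifts only under a preset correlation between genes. Of 28 lists tested with limma's camera, 9 passed with the correlation set to 0.01. Higher after TBI than other genes were the choroid plexus, interferon, microglia and oligodendrocyte lists. The ribosomal, endothelial, excitatory synapse, homeostatic astrocyte and ion channel lists were lower. With an estimated correlation 0 lists passed, and the adjusted p was 0.788 for each of these 9. The directional and mixed fry tests also called 0 lists, as did the exact permutation test of the list scores per library. The permutation test could hardly have called any. Its smallest possible p of 0.00794 passes adjustment over 28 lists only if several lists reach it together, so its 0 is weak evidence. No member of any list passed adjustment over all loci. Adjusted over the list alone, 1 member of 1 list passed, Cldn5. Of the 9 lists, 7 lost the call when at least 1 of the 10 libraries was left out. The choroid plexus and ribosomal lists kept it in those fits.

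Immune genes leaned upward in part of the injured libraries. Of 30 microglia and macrophage genes 27 had a higher mean after TBI (camera adjusted p = 0.000526 with the preset correlation, adjusted p = 0.788 with an estimated correlation). The secreted phosphoprotein Spp1 was at 0.939 ± 0.480 FPKM in sham and 3.91 ± 4.32 after TBI, and the integrin Itgam at 2.14 ± 0.568 and 3.34 ± 1.23. The list score was 0.65 in TBI 3 and 0.41 in TBI 1, and between -0.30 and -0.07 in the other 3 injured libraries, against -0.39 to 0.20 in sham. Without TBI 3 the adjusted p of this list was 0.615. TBI 3 also had the highest blood cell score of the 10 libraries (0.99) and the highest alpha globin value, at 992 FPKM, and microglia and blood scores had a Spearman correlation of 0.855 over the libraries. Of 27 interferon response genes 26 had a higher mean (adjusted p = 0.000193, and 0.788 as adjusted p with an estimated correlation). Among them were Mx1, at 3.52 ± 5.36 and 7.12 ± 4.62 FPKM, and the transcription factor Stat2, at 8.83 ± 0.453 and 9.97 ± 0.843. The interferon score was 0.67 in TBI 1, 0.43 in TBI 3 and 0.07 in TBI 5, but -0.30 in TBI 2 and -0.18 in TBI 4. Sham 4, at 0.49, lay above every injured library except TBI 1, and the other sham libraries lay between -0.38 and -0.10. Without TBI 1 the adjusted p of the interferon list was 0.0753. The matrix and meninges list was also high in TBI 1, with a score of 1.61.

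The other inflammatory lists did not pass in the fit reported here, although some passed with the preset correlation when 1 library was left out or under other alternatives. Of 22 complement and antigen presentation genes 16 had a higher mean (adjusted p = 0.115), led by C3 and by RT1-Ba, a class II histocompatibility gene at 0.685 ± 0.682 and 1.16 ± 0.984 FPKM. Some RT1 genes are near-identical copies of each other, so reads can be divided among those. The complement list passed as higher without sham 2 (adjusted p = 0.0472), sham 4 (1.30e-05), TBI 2 (0.00328) or TBI 4 (0.00763). It also passed as higher with both choroid plexus and matrix scores as covariates. But its score difference of 0.21 was 0.0068 without TBI 1 (0.718) and -0.10 with libraries 2 to 5 (0.105). Of 18 cytokine and chemokine genes 7 had a higher mean (adjusted p = 0.863). Csf1, a growth factor for microglia, was at 4.08 ± 0.309 and 4.84 ± 0.224 FPKM without overlap, and Cxcl14 at 55.4 ± 7.95 and 48.8 ± 2.09. With libraries 2 to 5 the cytokine list passed as lower (score difference -0.28, adjusted p = 0.0115). Of 21 reactive astrocyte genes 13 had a higher mean (adjusted p = 0.614), with Cd44 at 3.49 ± 0.680 and 4.001 ± 0.341 and S100a10 at 23.8 ± 3.80 and 18.4 ± 3.87; it passed as higher without sham 4 (0.0378), but its score difference of 0.048 was -0.16 without TBI 1. Of 7 blood cell genes 6 had a higher mean (adjusted p = 0.115), with the shared locus of the alpha globins Hba1 and Hba2 at 355 ± 260 and 540 ± 322 and Hbb-b1 at 8.10 ± 6.83 and 11.2 ± 5.43. The blood cell list passed without sham 2 (0.00516) or TBI 4 (0.0249).

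Vascular genes leaned downward in their means. Of 26 endothelial and pericyte genes 22 had a lower mean after TBI (camera adjusted p = 5.40e-05 with the preset correlation, adjusted p = 0.788 with an estimated correlation). Cldn5 passed limma's test adjusted over the list alone, with an adjusted p of 0.0124 by limma, and was lower in 5 of 5 injured libraries. Since 28 lists were each adjusted in this way, 1 such call can arise by chance. That call was lost under quantile normalization (adjusted p = 0.0910 by limma), with the replicate block (0.102) and with the choroid plexus score as covariate (0.0507), but kept with both choroid plexus and matrix scores (0.0189) or the matrix score alone (0.00589), while its log2 difference of -0.46 stayed between -0.54 and -0.39 in all 29 alternatives. Esam, an endothelial adhesion molecule, was at 12.3 ± 2.72 and 9.39 ± 1.08 FPKM, and the locus shared by the drug efflux pumps Abcb1a and Abcb1b at 8.81 ± 2.04 and 6.78 ± 0.260. The list score was 0.60 in TBI 1 and between -0.34 and -0.22 in the other 4 injured libraries. In sham it was 0.80 in sham 4 and 0.40 in sham 2, but -0.22, -0.20 and -0.26 in sham 1, sham 3 and sham 5, much like those injured libraries. Sham 2, sham 4 and TBI 1 also had the highest matrix and meninges scores. Without sham 4 the adjusted p of the endothelial list was 0.0554.

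Choroid plexus genes had the widest range of the lists shown. Of 23 genes 22 had a higher mean after TBI (camera adjusted p = 2.16e-06 with the preset correlation, adjusted p = 0.788 with an estimated correlation). The score was -0.73 ± 2.01 in sham and 0.73 ± 1.87 after TBI (SD, n = 5), with an exact permutation p of 0.325. Transthyretin (Ttr), the most abundant choroid plexus transcript, ran from 34.5 to 31400 FPKM in sham and from 72.7 to 32233 after TBI. Its log2 difference was 2.83 with a 95% interval of -2.005 to 7.67. The bicarbonate transporter Slc4a5 was at 18.4 ± 27.4 and 44.3 ± 45.2, the prolactin receptor Prlr at 3.99 ± 5.39 and 11.1 ± 11.7, and Tmem212 at 3.05 ± 1.75 and 4.85 ± 1.71. Of 26 matrix and meninges genes 16 had a higher mean (adjusted p = 0.715). This list passed as higher without sham 4 (score difference 0.43, adjusted p = 0.00358) and as lower without TBI 1 (-0.29, adjusted p = 0.0110). Their score was 1.05 in sham 2, 1.28 in sham 4 and 1.61 in TBI 1, and below 0 in the other 7 libraries. The collagen Col8a1 was at 3.89 ± 4.66 and 14.1 ± 17.9 FPKM, and Slc47a1 at 0.652 ± 0.649 and 1.22 ± 1.23. Col8a1 was lowest, at 0.061 to 1.30 FPKM, in sham 1, sham 4, sham 5 and TBI 2, the libraries with the least Ttr. In the others it was at 4.12 to 45.1.

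Neuronal lists that passed with the preset correlation did so through a single injured library. Of 36 excitatory synapse genes 33 had a lower mean after TBI (camera adjusted p = 0.000193, adjusted p = 0.788 with an estimated correlation). Of 30 ion channel and calcium genes 25 had a lower mean (adjusted p = 0.000651, and 0.788 as adjusted p with an estimated correlation). The excitatory synapse score was -0.63 in TBI 1 and between -0.03 and 0.12 in the other injured libraries, and without TBI 1 the adjusted p was 0.718 for this list and 0.237 for the ion channels. Both calls were also lost with the choroid plexus score as covariate (0.0652 and 0.0716), but kept with both choroid plexus and matrix scores or the matrix score alone. The scaffold Shank1 was at 99.1 ± 22.6 and 78.7 ± 16.9 FPKM, Cplx2, which binds the release machinery, at 317 ± 69.1 and 257 ± 65.3, and Rims1 at 47.3 ± 4.71 and 41.4 ± 7.50. Among the channels, the potassium channel Kcnc1 was at 21.8 ± 1.07 and 18.2 ± 4.11 FPKM and the calcium channel subunit Cacnb4 at 13.7 ± 2.87 and 11.2 ± 1.01.

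Other neuronal lists did not pass in the fit reported here. Of 28 inhibitory neuron and GABA genes 14 had a lower mean (adjusted p = 0.614), and the list's median lay just above 0 while its mean and test pointed down. The receptor subunit Gabrd was at 16.3 ± 3.16 and 12.6 ± 3.12 FPKM. Of 29 activity-induced genes 21 had a lower mean (adjusted p = 0.0573), with the nuclear receptor Nr4a2 at 23.7 ± 2.38 and 17.5 ± 5.52 and Ier5 at 27.9 ± 6.72 and 19.5 ± 4.81. This list lay at the threshold and passed in 9 of 29 alternatives, among them no filter (adjusted p = 0.0288), the replicate block (0.0207) and the first residual component (0.0315). It also passed without sham 4 (0.00162), TBI 4 (0.00578) or TBI 5 (0.000352), while without TBI 1 its adjusted p was 0.520 and with an estimated correlation 0.788. Of 18 hippocampal subfield genes 10 had a lower mean (adjusted p = 0.352). Amigo2 was at 6.30 ± 1.87 and 8.45 ± 1.17. Of 24 genes of neighbouring thalamus, striatum and cortex 13 had a lower mean (adjusted p = 0.614), with the adenosine receptor Adora2a at 1.47 ± 0.245 and 1.17 ± 0.0894. The mean of this list lay above 0 while its median and test pointed down. With libraries 2 to 5 this list passed as lower (score difference -0.068, adjusted p = 0.0350). Of 19 neurogenesis and proliferation genes 13 had a higher mean (adjusted p = 0.0822), with the replication clamp Pcna at 29.9 ± 1.65 and 33.8 ± 2.35 and Igfbpl1 at 2.72 ± 2.05 and 6.004 ± 4.60. Igfbpl1 was at 0.802 to 2.11 FPKM in sham 1, sham 4, sham 5 and TBI 2, the libraries with the least Ttr. In the others it was at 3.38 to 13.4, and its log2 difference of 0.90 ran from 0.16 to 1.36 over the alternatives. The neurogenesis list passed in 5 of 29 alternatives. These were without sham 1 (0.0433) or sham 4 (0.0499), with both scores or the choroid plexus score as covariates, and with libraries 2 to 5 but not sham 4.

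Macroglial lists moved in different directions. Of 29 oligodendrocyte and myelin genes 25 had a higher mean (camera adjusted p = 0.00566 with the preset correlation, adjusted p = 0.788 with an estimated correlation). Transferrin (Tf) was at 390 ± 135 and 562 ± 204 FPKM, the gap junction protein Gjb1 at 9.88 ± 1.09 and 12.0 ± 2.16, and Tspan2 at 42.0 ± 8.33 and 48.3 ± 8.60. Tf followed choroid plexus content, with a Spearman correlation with Ttr of 0.879 over the 10 libraries, and its log2 difference of 0.51 was 0.12 with the choroid plexus score as covariate. This call was lost without sham 2 (adjusted p = 0.501), without TBI 3 (0.313) or without TBI 5 (0.498). Of 13 oligodendrocyte precursor genes 11 had a higher mean (adjusted p = 0.323), among them Neu4 at 3.27 ± 0.427 and 4.37 ± 1.31, while Cspg5 was at 95.9 ± 2.82 and 87.9 ± 10.7. The precursor list passed in 5 of 29 alternatives. These were without TBI 1 (0.0193), with libraries 2 to 5 (0.0115, also without sham 4 and on named loci), and with the choroid plexus score as covariate. Of 19 homeostatic astrocyte genes 15 had a lower mean (adjusted p = 0.000651, and 0.788 as adjusted p with an estimated correlation). The neurotensin receptor Ntsr2 was at 89.7 ± 12.8 and 75.8 ± 7.99 and the glycolytic enzyme Aldoc at 544 ± 47.4 and 465 ± 77.3. The astrocyte call was lost without sham 5 (adjusted p = 0.0939) and with the choroid plexus score as covariate (0.0652), but kept with both choroid plexus and matrix scores or the matrix score alone.

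Of 50 ribosomal protein genes 39 had a lower mean after TBI (camera adjusted p = 3.50e-05 with the preset correlation, adjusted p = 0.788 with an estimated correlation). The shift was small, with a median log2 difference of -0.10. Rpsa was at 111 ± 11.2 and 97.1 ± 7.54 FPKM and Rps10 at 8.59 ± 3.57 and 4.46 ± 0.353. Ribosomal protein genes have many processed copies, so the values of single members are uncertain.

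Metabolic, stress and regulatory lists did not pass in the fit reported here, and the score differences of oxidative phosphorylation, glycolysis, heat shock and lipid genes turned positive under quantile normalization. Of 50 oxidative phosphorylation genes 35 had a lower mean (adjusted p = 0.163), with Ndufb3 at 63.0 ± 13.6 and 49.7 ± 3.64 FPKM and Atp5f1 at 1.29 ± 0.652 and 2.43 ± 0.883. This list passed as lower without sham 3 (0.00646), sham 4 (0.000370) or sham 5 (0.0326). Of 25 glycolysis and glucose transport genes 13 had a lower mean (adjusted p = 0.982), with the glucose transporter Slc2a1 at 65.3 ± 12.5 and 56.4 ± 7.09. Of 26 lipid and cholesterol genes 14 had a lower mean (adjusted p = 0.986), while the cholesterol exporter Abca1 was at 5.36 ± 0.706 and 7.07 ± 0.826 and lipoprotein lipase (Lpl) at 27.2 ± 8.46 and 42.3 ± 18.5. Of 32 oxidative and heat shock genes 17 had a lower mean (adjusted p = 0.505), with the chaperone Dnajb1 at 30.4 ± 2.36 and 25.8 ± 1.60 and Xbp1 at 66.8 ± 5.78 and 58.0 ± 5.16. Of 22 cell death and p53 genes 13 had a higher mean (adjusted p = 0.502), with Mdm2 at 12.8 ± 1.84 and 15.1 ± 2.32 and Bbc3 at 4.23 ± 0.379 and 3.57 ± 0.642. Of 19 glucocorticoid response genes 12 had a lower mean (adjusted p = 0.323). The transcription factor Zbtb16 was at 18.7 ± 4.87 and 12.1 ± 2.76 without overlap, and the kinase Sgk1 at 59.4 ± 4.75 and 82.6 ± 25.8. Of 25 neurotrophin and growth genes 15 had a lower mean (adjusted p = 0.715), although the mean of the list lay above 0, with Cntf at 3.25 ± 0.501 and 4.59 ± 1.05 and Rtn4r at 53.0 ± 7.79 and 41.8 ± 13.1. Of 19 DNA methylation and chromatin genes 9 had a lower mean (adjusted p = 0.844), and median and mean lay above 0 while the test pointed down. In that list Mbd3 was at 52.4 ± 3.09 and 43.3 ± 4.74 and Hdac5 at 35.5 ± 2.58 and 31.0 ± 1.13, both without overlap.

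**Figure D2:**
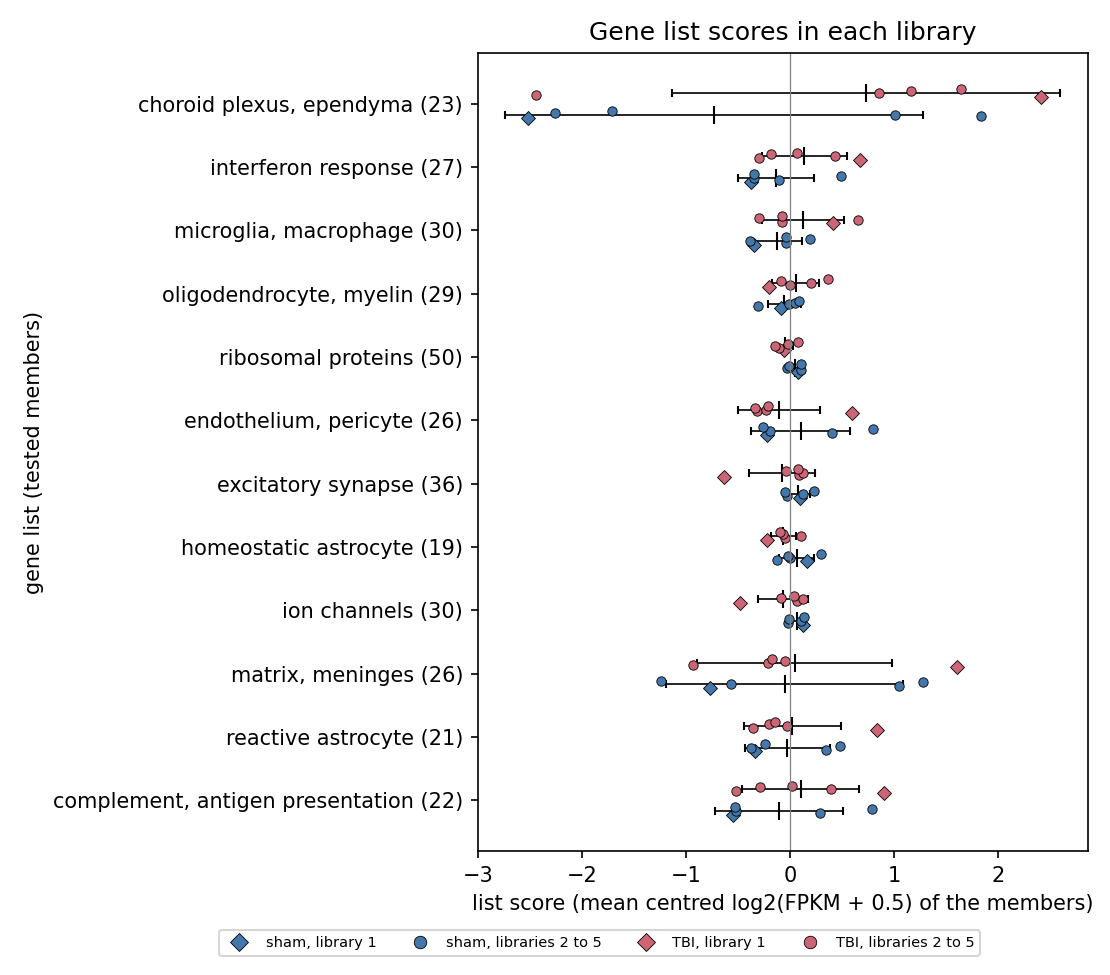
Scores of 12 gene lists in each library, as the mean centred log2(FPKM + 0.5) of the members, with tested members in parentheses, sham in blue, TBI in red, diamonds for the libraries numbered 1 and bars for mean ± SD of 5 libraries. The choroid plexus score spans -2.52 to 2.41 over both groups, and TBI 1 lies apart from the other injured libraries for the excitatory synapse list at -0.63.

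Libraries differed in ways that the groups do not describe. TBI 1 had a median Spearman correlation across loci of 0.919 with the other libraries, which themselves had medians of 0.961 to 0.972, and it took an extreme place on the first principal component (36.4% of the variance). In TBI 1 and sham 1 the FPKM of several genes that occupy more than 1 locus were divided differently between the loci than in the other 8 libraries. The examples named here were chosen after their values were seen. Of the desaturase Scd, 2.02% of the FPKM in sham 1 and 0.805% in TBI 1 lay on XLOC_002886, against 55.9% to 72.1% in the others. Klf9, a transcription factor induced by glucocorticoids, had 100% and 99.5% on XLOC_001281, against 42.8% to 66.4%. The pyruvate dehydrogenase subunit Pdha1 had 10.3% and 4.54% on XLOC_024845, against 55.1% to 62.8%. Over all loci 195 differed between the pair and the other 8 libraries in a limma fit that also held the group. The next of the 25 pairs of a sham and a TBI library was sham 4 with TBI 1, at 118, so part of this count follows TBI 1. With a term for this pair in the comparison of TBI with sham, 0 loci passed and 10 lists did, all 9 of the above among them. With libraries numbered 2 to 5 alone, 0 loci passed, 865 had an unadjusted p under 0.05, and 10 lists passed with the preset correlation. Only 3 of the 9 lists were among these, namely the endothelial, oligodendrocyte and ribosomal lists.

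**Figure D3:**
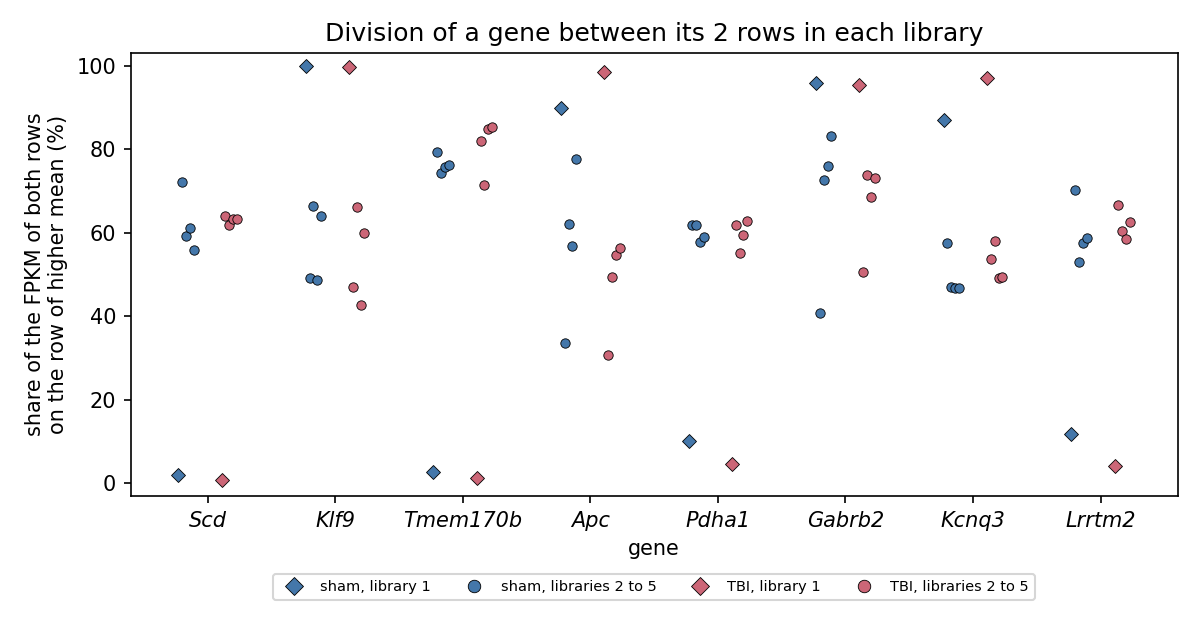
Share of a gene's FPKM on the locus of higher mean, in percent of its 2 loci, for 8 genes in each library, with sham in blue, TBI in red and diamonds for the libraries numbered 1. For Scd the libraries numbered 1 are at 2.02% and 0.805% while the other 8 lie between 55.9% and 72.1%.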

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

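The tests of the libraries numbered 1, of the choroid plexus genes and of tissue share in TBI 1 were chosen only after those results were seen; the bound on the correlation of TBI 1 was set before it was computed. A library was singled out where its gap to the nearest of its group exceeded 0.71 of the group's range. This held for 16 of 228 groups of 5 values, where chance gives about 11.4, and TBI 1 accounts for 11 of the 16. Many of these values are not independent of each other.

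TBI 1 stood apart from the other 4 injured libraries in list scores: 0.84 for reactive astrocytes (others -0.35 to -0.03), 0.71 for cytokines (others -0.35 to -0.05), 0.60 for endothelium, -0.63 for the excitatory synapse and -0.41 for lipid genes (others 0.06 to 0.16). The lipid score is lowered by the Scd locus XLOC_002886, at 4.80 FPKM in TBI 1 against 427 to 558 in the libraries numbered 2 to 5. The median of the lipid genes, which 1 locus hardly moves, was 0.39 lower in TBI 1 than in the other libraries. It was low for Shank1 at 50.2 FPKM (others 81.5 to 95.4), Kcnc1 at 11.0 (19.2 to 21.2), Dnajb1 at 23.0 (26.2 to 26.9) and Xbp1 at 49.1 (58.0 to 61.5). Its first principal component was 88.5 where the others lay between -26.1 and -2.42, and its median Spearman correlation was 0.919. A larger share of meninges, choroid plexus and vessels is a candidate explanation, since the matrix genes were 1.78 higher in TBI 1 on the log2 scale and the choroid plexus genes 3.18 higher than in the other libraries. As the whole cause it would lower neurons, astrocytes and oligodendrocytes alike. The medians of these lists were all lower in TBI 1, from -0.74 for the excitatory synapse to -0.28 for homeostatic astrocytes. This gap of 0.46 was reached by 2 of the other 9 libraries, sham 1 at 0.61 and TBI 5 at 0.50, so the gap alone does not decide whether tissue share was the whole cause. A first measure, the gap in standard errors from resampled genes (5.38), was set aside after it was seen, because it leaves out the spread between libraries. Sham 2 and sham 4 had matrix scores of 1.05 and 1.28, against 1.61 in TBI 1, but excitatory synapse scores of -0.03 and -0.05. These values argue against tissue share as the whole cause. They do not exclude it, since the choroid plexus scores of sham 2 (1.84) and sham 4 (-2.26) were below that of TBI 1 (2.41). Removing the 195 loci that differ in the libraries numbered 1 raised the median correlation of TBI 1 to 0.926, below the lowest of the others at 0.961. These 195 were a small part of the loci, and loci placed differently but not called stayed in. The test therefore had little chance to restore the correlation and does not decide whether locus placement is the cause. A stronger injury in the animal behind TBI 1 was not tested and stays open.

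Ttr was at 72.7 FPKM in TBI 2, where the other injured libraries lay between 9079 and 32233. Choroid plexus tissue carried along in dissection is a candidate explanation of the range in both groups, since 19 of 22 other tested members (86.4%) had a Spearman correlation with Ttr of at least 0.7 over the 10 libraries. The exceptions were Tmem212, Ccdc153 and Rarres2. Against injury as the whole cause stands the range within sham, which was 88.4% of the range over all 10 libraries. An added effect of injury on these genes stays open.

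Sham 1 was at 49.7 on the second principal component, where the other sham libraries lay between -20.1 and -2.36. It shared with TBI 1 loci on which both lay over 1 log2 unit outside the other 8 libraries. There were 63 such loci for this pair, 52 below and 11 above, against 19 for the next of 45 pairs, sham 2 with TBI 1, and 18 for sham 4 with TBI 1, so part of the signal follows TBI 1. The count of 63 for the pair is consistent with a library, sequencing or mapping batch shared by both, although the labels name none. Reads placed on another locus of the same gene may account for examples such as Scd, but over the 81 genes with several loci the other loci differed the opposite way in 59.3% (95% Wilson interval 48.4% to 69.3%), which neither excludes nor requires it. The bound against this explanation was first set at 60% or less, which the value meets. After it was seen, the bound was moved to the upper end of the interval, so the first bound would have counted against the explanation. A first measure, the median difference of the summed loci against that of the differing loci (0.32 against 1.95 on the log2 scale, a ratio of 0.165), lay within the bound set for placement and was set aside after it was computed, because a sum follows its larger locus with or without such placement. Injury cannot produce this pattern alone, since 1 of the pair is a sham library.

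Plac9 was at 4.22 FPKM in sham 4 against 25.3 to 43.2 in the other sham libraries. Rtn4r was at 39.9 FPKM in sham 1 against 53.3 to 59.9 in the other sham libraries. Kcnk13 was at 0.955 FPKM in TBI 4 against 1.33 to 1.45 in the other injured libraries.

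Other splits of the 10 libraries into 2 groups of 5 were fitted for 100 of the 126 possible splits. For the count of loci past adjustment in limma's test the comparison says nothing, since the real count is 0 and all 100 splits must give at least as many; the highest other split gave 30. Chance cannot be excluded for the 477 loci at an unadjusted p under 0.05, which 59 of the 100 splits reached, with 2598 as the highest other. The same holds for the 9 lists past camera with the preset correlation, since 61 of the 100 splits gave as many and the highest other gave 19. Splits with several times the real count point to a structure of the samples other than the groups. The split with 30 loci past adjustment put sham 1, sham 2, TBI 1, TBI 2 and TBI 3 together. The split with 2598 put sham 1, sham 2, TBI 1, TBI 2 and TBI 4 together. Both keep the libraries numbered 1 on the same side, but 5 of the 7 splits with loci past adjustment part them. Among these is sham 1, sham 2, TBI 2, TBI 3 and TBI 4 against the rest, with 5 loci past adjustment and 2347 at an unadjusted p under 0.05. The median at that p was 559 in splits that keep the pair together and 603 in splits that part it, so the structure does not follow this pair alone. A term for the pair in the real comparison gave 0 loci past adjustment and 757 at an unadjusted p under 0.05.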

How the results depend on the processing

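Results under a term for the libraries numbered 1, libraries 2 to 5, list scores as covariates or summed loci were chosen after seeing the data. The count of changed loci was 0 in limma's test under all alternatives except without sham 4, where it was 1 (Plac9); over the leave-one-out fits it ran from 0 to 1. Loci at an unadjusted p under 0.05 ranged from 320 to 1390. Of the 80 genes chosen by the naming rule, not all of them described here, 74 kept their sign in all of up to 29 alternatives in which they were tested and 1, Plac9, was called in any. The list scores gave 0 calls throughout, which the small number of possible assignments made likely in advance. The 9 lists became 5 with array weights, 4 of the 9 and the glycolysis list, and 0 with an estimated correlation or with fry. With the choroid plexus score as covariate, 5 of the 9 passed; the astrocyte (adjusted p 0.0652), excitatory synapse (0.0652) and ion channel (0.0716) lists were lost, and the choroid plexus list was not tested. With both scores 8 of the 9 passed, again without the choroid plexus list, and with the matrix score all 9. The number was 7 to 14 over the leave-one-out fits, 14 without sham 4. Over all 29 alternatives, lists outside the 9 passed in their direction 35 times, 9 times the activity-induced list. Lists with a member past adjustment over the list alone were 1, and became 0 with quantile normalization, with the replicate block or with the choroid plexus score as covariate, 5 with array weights or with the first residual component, 2 with the term for the libraries numbered 1 or with libraries 2 to 5 (also without sham 4 and on named loci), and 1 to 2 over the leave-one-out fits.

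The library numbers were not taken as pairs, on a check of correlations alone. Deviations of libraries of the same number correlated at 0.011, -0.31, 0.058, -0.070 and 0.32 for numbers 1 to 5, and 1 of 10 libraries correlated best with its own number. With the replicate block, 0 loci passed, 695 had an unadjusted p under 0.05, 10 lists passed, with the activity-induced list as the added list (adjusted p 0.0207), and Cldn5 had an adjusted p of 0.102 over its list.

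Differences changed sign, and the cause was not tested. Gfap was 0.018 with quantile normalization, 0.015 with libraries 2 to 5 (named loci too) and -0.25 to 0.12 over the leave-one-out fits. Slc17a7 was 0.028 with quantile normalization, 0.055 with array weights, 0.11 with libraries 2 to 5 (named loci too), 0.016 with these but not sham 4, and -0.16 to 0.081 leaving out 1 library. Vim was -0.45 with libraries 2 to 5 (named loci too), -0.15 with the choroid plexus score, -0.061 with the matrix score, and -0.30 to 0.40 leaving out 1 library. Mbp ran from -0.20 to 0.032 leaving out 1 library. Ttr, at 2.83 in the comparison reported, was -0.25 with both scores, -0.12 with the choroid plexus score and -0.54 with libraries 2 to 5 but not sham 4, where Slc4a5 was -0.013 in place of 2.31.

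List directions relative to other genes turned in 79 of the fits of single lists. The values here are score differences. With array weights or the replicate block these are computed without the weights or the block and so keep their value. Without a filter cytokines were 0.017, and with a mean of at least 2 FPKM glycolysis was 0.0067 and lipid genes -0.00087. With quantile normalization oxidative phosphorylation was 0.021, glycolysis 0.026, heat shock 0.013 and lipid genes 0.020. Camera's direction turned with array weights for matrix (0.097), GABA (-0.016), oxidative phosphorylation (-0.030), glycolysis (-0.0011) and lipid genes (-0.00087), with the block for glycolysis (-0.0011) and lipid genes (-0.00087), and with the term for the libraries numbered 1 for glycolysis (-0.0011). With libraries 2 to 5 (named loci too) reactive astrocytes were -0.23, complement -0.10, matrix -0.47, excitatory synapse -0.0052, GABA 0.14, oxidative phosphorylation 0.020, glycolysis 0.088, p53 -0.067 and lipid genes 0.093. Of these, matrix (adjusted p 0.00273), GABA (0.0162), glycolysis (0.0121) and lipid genes (0.00763) passed in the turned direction. Without sham 4 as well, reactive astrocytes were -0.089, matrix -0.089, choroid plexus -0.070 (1.46 in the comparison reported), GABA 0.14, glycolysis 0.052, p53 -0.049 and lipid genes 0.076, and GABA and lipid genes passed (0.0111 each). With both scores as covariates GABA was 0.062, glycolysis 0.014 and lipid genes 0.0045. With the choroid plexus score reactive astrocytes were -0.080, matrix -0.28, GABA 0.088, glycolysis 0.028, p53 -0.017 and lipid genes 0.032, and with the matrix score glycolysis was 0.0044.

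Over the leave-one-out fits reactive astrocytes ran from -0.16 to 0.17, complement from 0.0068 to 0.43, cytokines from -0.19 to 0.14, matrix from -0.29 to 0.43, GABA from -0.071 to 0.076 and oxidative phosphorylation from -0.072 to 0.022. Glycolysis ran from -0.041 to 0.055, p53 from -0.017 to 0.087, neurotrophins from 0.0011 to 0.13, lipid genes from -0.042 to 0.10, chromatin from -0.00053 to 0.021 and oligodendrocyte precursors from 0.016 to 0.14. Depth is unknown, so its limit cannot be given, and the planned edgeR alternative was not run because whole reads could not be recovered.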

Other observations

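The tests of this part were set before the adjusted scores were computed, but after the unadjusted list results were seen, which had exact p of 0.270 for microglia and 0.722 for complement without C3. Among the immune genes, C3 lay above the sham mean in 5 of 5 injured libraries, from 2.53 FPKM in TBI 4 to 13.9 in TBI 3, against 1.49 to 3.08 in sham. It did not pass adjustment (limma's adjusted p = 0.988), and its log2 difference ran from 1.09 to 1.65 over the alternatives.

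A hypothesis was that injury raises microglial genes once choroid plexus and matrix content are modelled, since both vary strongly between libraries. With these 2 scores as covariates the microglia and macrophage score was 0.28 higher after TBI, with an exact permutation p of 0.278 when the model was refitted for each assignment, and 4 of 5 injured libraries lay above the adjusted sham mean. Permuting the adjusted scores themselves gave p = 0.135, which is not exact, because the adjustment was fitted with the true groups. The hypothesis stays open, since neither p passed and the injured libraries did not all lie below the adjusted sham mean. The latter was the bound set against it, but would seldom be met even without any effect, so this bound decides little.

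A similar hypothesis was that C3 is raised together with the other complement and antigen presentation genes. Without C3 the adjusted score of that list was 0.15 higher after TBI, with an exact permutation p of 0.444, and 3 of 5 injured libraries lay above the adjusted sham mean. Permuting the adjusted scores gave p = 0.286, again not an exact p. The hypothesis stays open as well, under the same bound and with the same limit.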
